A study of Mus musculus and Homo sapiens with 6 samples.

How the data were processed

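CUT&Tag, in which a transposase tethered by an antibody inserts sequencing adapters next to the antibody's target, was done on 6 samples: in mouse embryonic fibroblasts (MEFs) with the S9.6 antibody, which binds RNA-DNA hybrids, in Mcm8 wild-type (WT) and Mcm8 knockout (KO) cells and without an antibody in WT cells, and in HEK293, a human embryonic kidney cell line, with an anti-FLAG antibody after transfection of a FLAG-MCM8 plasmid, with S9.6 and without an antibody. Libraries were amplified for 11 PCR cycles, per the labels' protocols. Trimmomatic, Bowtie2 and MACS2 2.1.2 and the builds mm10 and hg19 are named in the submitters' processing notes. Whether a control library entered the peak calling, and how duplicate reads were treated, is not given in the sources used here.

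The deposited files are 1 peak list per sample. The authors' list gives for each peak its position, a score equal to 10 times the −log10 p rounded down, the fold enrichment over the local background, the −log10 p, the −log10 q and the summit. The fold enrichment and −log10 values are the authors' own and were used only to describe, rank or filter peaks within their own list. The lists held no identical intervals and no peak outside the numbered chromosomes, X and Y. The lowest −log10 p of the lists lay between 3.00 and 3.05.

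The pileup behind each peak, that is the number of fragments over its summit, was recovered from the deposited fold and −log10 p as the whole number whose Poisson tail gave both, within 0.01 of the −log10 p. This held for all peaks of 5 lists and for all but 1 of the 9806 FLAG-MCM8 peaks. On 5000 simulated peaks the true pileup was returned for 100%. The lowest background of a list, the shortest peak as the fragment length and MACS2's preset genome size, which is an assumption, gave the number of fragments per library, given here in units of 1000000 fragments (M). The number was 12.1 M for WT S9.6, 10.7 M for KO S9.6 and 1.35 M for the MEF library without antibody. It was 10.8 M for FLAG-MCM8 and 13.3 M for HEK293 S9.6. In the HEK293 list without antibody the lowest background equalled 1 fragment per 10 kb, so the 0.27 M it gives is an upper limit.

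Peaks of 2 lists were counted as shared when they overlapped by at least 1 bp. A share is given with its 95% Wilson interval, which covers counting error only, since PCR copies and neighbouring peaks are not independent. The chance level was the share over 1000 random circular shifts of the peaks within each chromosome. Lists with known overlap were tested on simulated data: with 30 percent of the KO peaks copied, 30.0% were returned as shared, and a randomly placed list shared 0.364% against 0.314% under shifts. The share was also computed in successive parts of 10% of a list ranked by p.

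Each group has 1 library, so no p-value was computed between conditions. The rule for named peaks, fixed before the data were examined, took the 10 peaks of largest fold in each class, ties ordered by p and position, with up to 30 genes per mouse comparison, and the 3 runs with most peaks among runs of at least 5 peaks spaced within 50 kb. Classes were defined after removing peaks that overlapped a peak of the library without antibody. Mouse peaks were matched to 49943 genes, 21887 of them protein-coding, of the RefSeq table of the same assembly as mm10. The table has no strand, so a peak within 1 kb of either end of a gene was counted as at a gene end and no promoter, exon or intron is given. No human annotation was used here, so HEK293 peaks are named by hg19 position. Some genes that the naming rule or the lists include are not reported here. A gene counted as having a peak when one overlapped the gene or the 1 kb on either side.

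The 12 gene lists fixed beforehand cover replication, homologous recombination and Fanconi, R-loop resolution, R-loop control loci, immediate-early, small non-coding RNA, fibroblast, epithelial, neural, blood, ribosomal protein and histone genes. The number of members with a peak is given with its percentile among 10000 random lists of protein-coding genes matched on gene length, as a description of these libraries. These random lists do not match how often genes have a peak. With more peaks in KO, a list rich in peaks in both genotypes can thus show a large KO to WT difference. The small non-coding RNA list has no such percentile in the text, since protein-coding genes do not match it.

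Alternatives set beforehand were an overlap of at least 50% of the query peak, the query summit inside the other peak, a −log10 q of at least 5, a fold of at least 5, lists of equal size, all contigs, and chance positions drawn among the peaks of all lists. Added after the data were seen were a q of at most 0.05 in both lists or in the query list alone, which was also applied to the gene-end shares and gene lists, shifts of 10 to 200 kb, removal of only those peaks without antibody that held at least 2 fragments, and a minimum number of fragments at the summit per 1000000 fragments of the library. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.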

Results

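CUT&Tag peaks of S9.6, an antibody raised against RNA-DNA hybrids, were listed for Mcm8 WT and KO MEFs, and peaks of FLAG-tagged MCM8, a helicase of the MCM family, and of S9.6 for HEK293 cells. Each cell type also had 1 library made without an antibody. Whether the S9.6 peaks mark RNA-DNA hybrids was not tested here. No group had a replicate, so differences between libraries carry no test of the condition. The KO library held 88.3% of the fragments of the WT library, and the MEF library without antibody 11.1%. In HEK293, the FLAG-MCM8 library held 80.9% of the fragments of the S9.6 library, and the library without antibody at most 2.03%. The median pileup at a summit was 10 fragments in WT and 9 in KO MEFs, 7 for FLAG-MCM8 and 10 for HEK293 S9.6. In the HEK293 list without antibody, 33736 of 35298 peaks (95.6%) rested on 1 fragment.

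**Figure D1:**
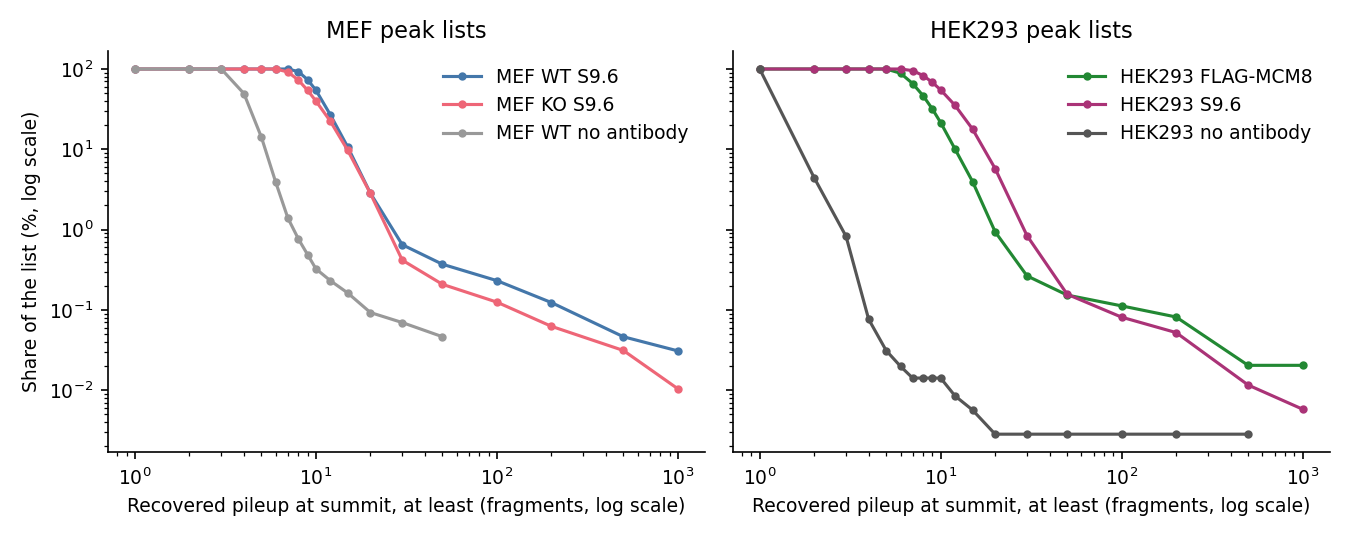
Share of each peak list (%, log scale) whose recovered summit pileup is at least the number of fragments on the x axis (log scale), for the 3 MEF lists and the 3 HEK293 lists. The HEK293 list without antibody falls at once because 95.6% of its peaks hold 1 fragment; the 1 FLAG-MCM8 peak whose pileup was not recovered is left out.

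The first comparison asked how S9.6 peaks differ between Mcm8 KO and WT MEFs. At Mcm8 itself (mm10 chromosome 2, 132816137 to 132844197) the KO list had 1 peak, at 132816436 to 132816690 with a fold of 3.31, and the WT list and the list without antibody had none. This peak does not check the knockout, since the deleted part is not given in the sources used here. The KO list held 9605 peaks covering 3.52 Mb and the WT list 6481 peaks covering 2.43 Mb. Of 21887 protein-coding genes, 5633 had a KO peak and 4164 a WT peak. Both lists had a peak at 2544 genes, where independent lists of these sizes would share 1072, the KO list alone at 3089 and the WT list alone at 1620. The 1072 treats all genes alike and does not allow for gene length. Among KO peaks, 83.5% (95% Wilson interval 82.8 to 84.2) had no overlapping WT peak, and among WT peaks 75.5% (74.4 to 76.5) had no KO peak. The shared part was above the level of random shifts: 16.5% of KO peaks against a mean of 0.211% (0.0625 to 0.396), and 24.5% of WT peaks against 0.308% (0.123 to 0.571). With chance positions drawn among the peaks of all 3 MEF lists, where unshared peaks count as possible positions by construction, the chance levels were 34.8% and 51.6%, above the observed shares.

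Peaks shared by both genotypes lay mostly at gene ends. Outside the peaks found without antibody, 61.0% (58.5 to 63.4) of the 1521 shared KO peaks had their summit within 1 kb of an end of a protein-coding gene, against 20.6% (19.7 to 21.5) of the 7974 KO-only peaks and 17.8% (16.7 to 18.9) of the 4876 WT-only peaks. In the MEF list without antibody the share was 5.15% (4.53 to 5.85), and random shifts of its peaks gave 3.13%. The contrast was smaller among peaks with a q of at most 0.05, where the share was 64.7% for shared KO peaks, 36.0% for KO-only and 29.9% for WT-only peaks. Shared peaks were also taller in their own list, with a median pileup of 13 fragments against 8 for KO-only and 9 for WT-only peaks. Among KO-only peaks, 28.1% had a q of at most 0.05, against 75.7% of the shared KO peaks. In the 10% of the KO list with the smallest p, 63.7% (60.6 to 66.7) of peaks overlapped a WT peak, and in the last 10% of the list 2.29% (1.52 to 3.45). For WT peaks overlapping a KO peak, the first 10% of the WT list gave 76.1% (72.7 to 79.2) and the last 6.17% (4.57 to 8.30).

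**Figure D2:**
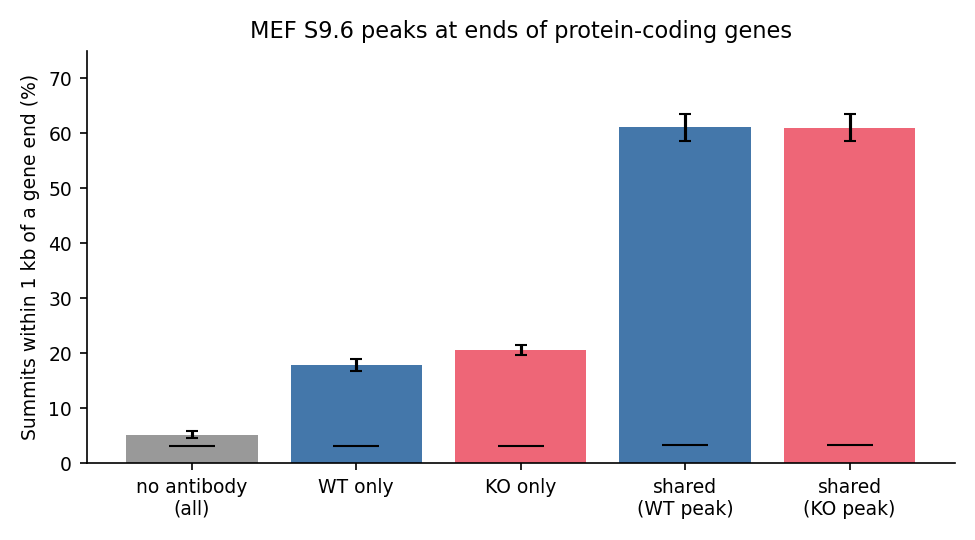
Share of MEF S9.6 peak summits within 1 kb of an end of a protein-coding gene (%), for the list without antibody and for WT-only, KO-only and shared peaks; error bars are 95% Wilson intervals and black dashes the mean of random shifts. Shared peaks reach 61.0%, KO-only peaks 20.6% and WT-only peaks 17.8%; among peaks with a q of at most 0.05 the shares were 64.7, 36.0 and 29.9%.

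The KO-only peak of largest fold lay on chromosome 12, 31350985 to 31351577, 72 bp inside an end of Dld, the dihydrolipoamide dehydrogenase of mitochondrial enzyme complexes, with a fold of 7.37. Next were Plpp1, a phospholipid phosphatase (chromosome 13, 112800575 to 112801237, fold 7.37), the neighbours Fbxl13 and Armc10 (fold 7.35), Bicdl1 (6.94), Tmem260 (6.94), Pwwp2a (6.74) and Fxr2, an RNA-binding protein related to FMRP (6.74). Casc1 with Etfrf1 (6.53) and Zranb3, a translocase that acts at stalled replication forks, with R3hdm1 (6.48) were also among the first 10. Further KO-only peaks lay at Pnpla8, Larp4b, Paip2b, Ric8b, Rsbn1, Pcf11, which acts in mRNA 3′ end formation, Hnrnpa1, a splicing regulator next to Cbx5, and Idi1, an enzyme of isoprenoid synthesis. Of the 30 KO-only peaks of largest fold, 27 lay within 1 kb of a gene and 23 had a summit within 1 kb of an end of that gene. The KO-only run with most peaks held 9 peaks over 189 kb of chromosome 15 (84654334 to 84843709) at Prr5, Arhgap8 and Phf21b.

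The WT-only peak of largest fold (6.73) lay outside genes on chromosome X, 169993752 to 169994358. Arl6ip1 (chromosome 7, 118129652 to 118130031, fold 6.30), Eef1e1 (6.15), Rc3h1, an RNA-binding protein of mRNA decay (5.94), Abracl (5.94) and Wee1, the kinase that restrains entry into mitosis (5.92), came next among those with a gene. Il1rl1, Uspl1 and Slc30a4 completed the first 10 together with a peak outside genes on chromosome 18, and Park7, Zfr and Arid1b stood further down. Of the 30 WT-only peaks of largest fold, 21 lay within 1 kb of a gene and 13 had a summit within 1 kb of an end of that gene. The WT-only run with most peaks held 9 peaks over 207 kb of chromosome 7 (141355398 to 141562215), a stretch with Taldo1, Rplp2, Cd151 and Polr2l among its genes.

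The shared peaks of largest fold were inside Kctd16 (chromosome 18, 40308037 to 40308431, fold 28.8 in KO and 28.7 in WT) and Zc3h7a (chromosome 16, 11143946 to 11144297, fold 26.2 in KO and 25.8 in WT), both far from the gene's ends. Peaks outside genes on chromosomes 3 and 11 and peaks inside Camk1d and Cdk8 followed. The pileup was 208 fragments in KO and 224 in WT at Kctd16, and 176 and 216 at Zc3h7a. The list medians were 9 in KO and 10 in WT. The library without antibody was shallow, so background at these tall peaks of both lists is not excluded. Further down the shared list, peaks lay at ends of Sdf2l1 (fold 7.64 in the KO list), Dstn (7.62), Gatad2a (7.62), Gsk3b, a kinase of Wnt signalling (7.48), Aco1 (7.35), Numb, a regulator of Notch (7.24), and the histone demethylase Kdm3a (7.18).

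Of the 24 replication helicase and origin genes, 12 had a KO peak and 8 a WT peak, at the percentiles 99.1 and 93.3 of random lists matched on gene length, and the difference between KO and WT lay at percentile 82.5. Orc2, Orc1, Orc6, Gins2, Cdt1 and Mcm4 had both, Mcm8, Mcm10, Orc4, Gins4, Mcm5 and Gmnn a KO peak alone, and Mcm7 and Cdc6 a WT peak alone. Cdt1 and Cdc6 also had a peak without antibody, which at Cdt1 overlapped the KO peak. Among the peaks at Mcm4, the fold was 6.45 in KO and 5.15 in WT, each relative to its own library's background. Of 22 homologous recombination and Fanconi genes, 11 had a KO peak and 7 a WT peak (percentiles 92.7 and 72.5, difference 80.1), among them Fancm, Blm, Rad52, Xrcc3 and Fancc in both lists and Rad54l, Fanci and Hrob in KO alone, and Fanca and Brca1 in WT alone. A peak without antibody was found at 4 of the 22, Wrn, Rad50, Rad51b and Rad51c. Of 21 genes of R-loop resolution, 7 had a KO peak and 4 a WT peak (percentiles 65.6 and 39.5, difference 72.7). Sin3a, Srsf2 and Thoc1 were among those with both, and the helicase genes Dhx9 and Ddx5 and the splicing factor gene Srsf1 a KO peak alone. None of these 21 genes had a peak without antibody. With peaks at a q of at most 0.05, the KO and WT numbers were 7 and 5 for replication, 6 and 6 for recombination and Fanconi and 5 and 4 for R-loop resolution genes.

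Loci often used as R-loop controls had a KO peak at 9 of 15 genes and a WT peak at 6 (percentiles 100 and 99.8, difference 92.5), with Egr1, Myc, Btbd19 and Rpl13a among those in both. Of 17 immediate-early genes, 9 had a KO peak and 5 a WT peak (percentiles 99.99 and 98.8). Jun, Jund, Ccn2, Myc and Egr1 had both, and Fos, Fosb, Junb and Ier3 a KO peak alone. The difference between KO and WT in this list lay at percentile 98.0 of random lists. Those averaged 2.42 KO and 1.65 WT genes and do not match this list's richness in peaks. The percentile therefore does not show a genotype difference particular to these genes. Of 77 ribosomal protein genes, 18 had a KO peak and 9 a WT peak (percentiles 99.7 and 87.7), and the difference lay at percentile 97.6. The same limit holds there, since the random lists averaged 9.28 KO and 6.17 WT genes. Rpl13a, Rps27a, Rps27l and Rps23 were among those with both, and Rpl7, Rpl11, Rps19 and Rpl30 were among 13 with a KO peak alone. At Rpl38 the KO peak overlapped a peak without antibody, and the R-loop control and immediate-early genes had none. With peaks at a q of at most 0.05, the KO and WT numbers were 3 and 2 for control loci, 6 and 5 for immediate-early genes and 8 and 4 for ribosomal protein genes, so most of the immediate-early difference rested on weaker peaks. Of 4 small non-coding RNA genes in the table, Rn7sk had both, Rnu12 a KO peak and Rmrp a WT peak.

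Of 16 fibroblast and matrix genes, 5 had a KO peak and 4 a WT peak (percentiles 52.0 and 59.0, difference 44.7), with Fn1, Vim, Col5a1 and Pdgfrb in both and Sparc in KO alone. Genes of other cell types served for comparison. Of 9 epithelial genes 1 had a KO peak (Cdh1) and 3 a WT peak (Krt18, Krt19 and Grhl2), at percentiles 18.4 and 87.0, and the difference lay at percentile 3.26. Of 9 neural genes 2 had a KO peak and 1 a WT peak (29.4 and 21.1, difference 57.4), and of 8 blood genes 1 had a KO peak and 1 a WT peak (20.8 and 34.3, difference 35.6). At a q of at most 0.05 no epithelial or blood gene had an S9.6 peak, and the neural list had 0 KO and 1 WT genes, so the epithelial difference rested on weaker peaks. Fibroblast genes then numbered 4 in KO and 1 in WT. Of 67 replication-dependent histone genes, 1 had a KO peak (H3c10) and 1 a WT peak (H3c15), at percentiles 25.5 and 45.9, with the difference at 30.1.

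Few MEF S9.6 peaks overlapped a peak of the library without antibody: 1.15% (0.951 to 1.38) in KO, where shifts gave 0.136%, and 1.23% (0.993 to 1.53) in WT, where shifts also gave 0.136%. The tallest peaks of all 3 MEF lists were among them, at the ribosomal RNA gene Rn18s-rs5 (chromosome 17, 39843177 to 39846690 in WT) and at places within 1 kb of Gm36876 and Lars2. Outside peaks without antibody, 9495 KO and 6401 WT peaks remained, a ratio of 1.48, and more KO than WT peaks were listed on each of the 19 autosomes. The ratio was 2.24 at a minimum of 1 fragment at the summit per 1000000 fragments of the library, 1 at a minimum of 3 (19 and 19 peaks) and 0.846 at a minimum of 5 (11 and 13 peaks), so the tallest peaks were not more numerous in KO. These few peaks included places of both lists, such as Kctd16 with 208 fragments in KO and 224 in WT. They say little about the weaker peaks. The library without antibody was shallow and came from WT cells alone, so a missing peak there does not show that a site lacks background.

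**Figure D3:**
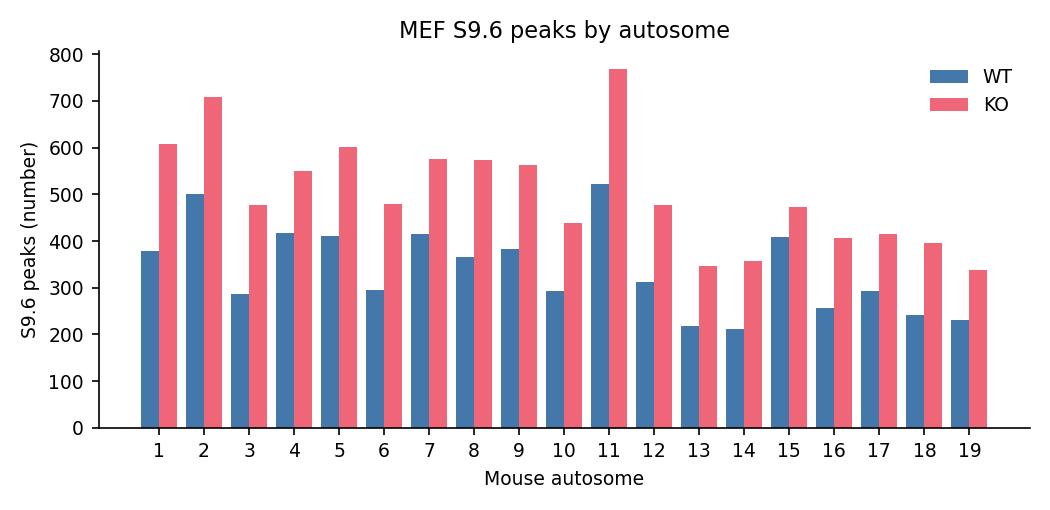
Number of S9.6 peaks per mouse autosome in the WT and KO lists, 1 library each. The KO bar is the taller one on all 19 autosomes.

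The HEK293 comparison asked whether FLAG-MCM8 and S9.6 peaks were found at the same places. Which construct each culture carried is known from the labels alone, so the shares below describe peaks of the library labelled FLAG-MCM8, and whether the S9.6 and no-antibody cultures were transfected is not given in the sources used here. On chromosome 20, which carries MCM8, the tallest FLAG-MCM8 peak absent from the other 2 lists held 52 fragments (26188860 to 26189383), against 2705 at a chromosome 17 peak. It lay close to 26189867 to 26190469, a place with a peak in all 3 HEK293 lists. The value at MCM8 itself was not examined. A q of at most 0.05 was reached by 1800 (18.4%) of the FLAG-MCM8 peaks and 10027 (58.1%) of the S9.6 peaks. Of 9806 FLAG-MCM8 peaks, 1664 (16.97%, 16.2 to 17.7) overlapped 1 of the 17247 S9.6 peaks, against a mean of 0.518% (0.296 to 0.836) under random shifts. Outside peaks without antibody the share was 16.3% (15.6 to 17.05) of 9543 peaks, against 0.4997% under shifts. From the other side, 9.64% (9.21 to 10.1) of S9.6 peaks overlapped a FLAG-MCM8 peak. The overlap was concentrated in peaks of small p: 51.5% (48.4 to 54.6) of the first 10% of the FLAG-MCM8 list and 3.78% (2.75 to 5.16) of the last 10%. When chance positions were drawn among the peaks of all 3 HEK293 lists rather than along chromosomes, so that unshared peaks count as possible positions by construction, the chance level was 29.3%, above the observed share.

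**Figure D4:**
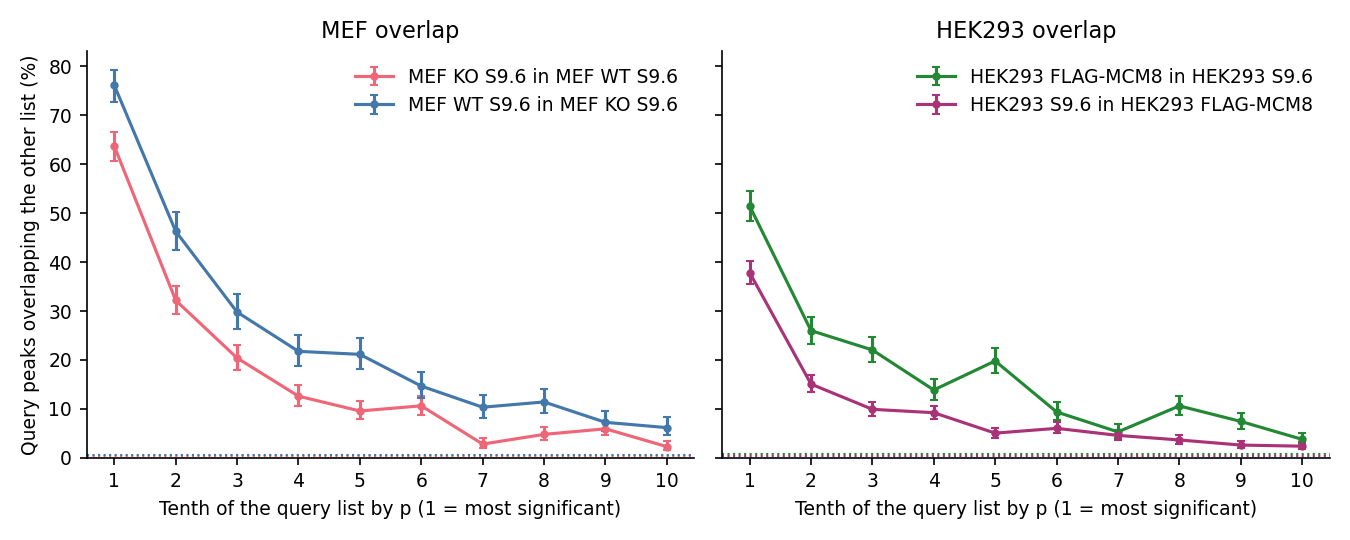
Share of peaks that overlap the other list (%), in successive parts of 10% of the query list ranked by p, for KO and WT MEF S9.6 peaks and for HEK293 FLAG-MCM8 and S9.6 peaks; error bars are 95% Wilson intervals and dotted lines the mean under shifts of 10 to 200 kb. The first 10% of FLAG-MCM8 peaks reach 51.5% and the last 3.78%.

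The FLAG-MCM8 peaks of largest fold with an S9.6 peak lay on hg19 chromosome 1, 91852783 to 91853150 (fold 21.4) and 156186231 to 156186703 (18.4), and on chromosome 7, 61968814 to 61969634 (14.4). The next in the FLAG-MCM8 list were a peak on chromosome 1, 569369 to 570076 (10.7), and peaks on chromosome 17, 41381687 to 41382357 (8.42) and 41399933 to 41401149 (8.36). The chromosome 1 places at 91852783 and 156186231 also led the shared S9.6 peaks, with folds of 23.05 and 21.1. In the FLAG-MCM8 list the local background there was 8.79 and 15.3 fragments, and 18.5 at the chromosome 7 place. The lowest background of that list was 1.00. The peak at 156186231 to 156186703 had the same edges in both antibody lists. After the chromosome 1 places, the next shared S9.6 peak by fold lay on chromosome Y, 10026720 to 10027592 (19.6, 54 fragments). The shared FLAG-MCM8 peaks also included one on chromosome Y, 9984743 to 9985540 (8.29). Whether these cells carry a Y chromosome was not examined. Apart from peaks found without antibody, no high-signal regions were removed here, so background at these places is not excluded. Shared FLAG-MCM8 peaks had a median pileup of 10 fragments and those without S9.6 one of 7.

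Among FLAG-MCM8 peaks without S9.6, the first by fold lay on chromosome 17, 62496041 to 62496934, with a fold of 10.1 and a −log10 p of 3740. A pair of further peaks stood 2 to 4 kb away, at 62499044 to 62499744 with a pileup of 2705 fragments and at 62500113 to 62500455 with 1137. Neither the S9.6 list nor the list without antibody had a peak at these 3 places. The next FLAG-MCM8 peaks without S9.6 were far lower, on chromosome 15, 49462183 to 49462646 (fold 6.49), chromosome 3, 138634697 to 138635234 (6.17), and chromosome 2, 223574054 to 223574525 (5.99). The run with most such peaks held 6 peaks over 152 kb of chromosome 11 (62537246 to 62689631).

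S9.6 peaks without FLAG-MCM8 numbered 15195 outside peaks without antibody. Those of largest fold lay on chromosome 16, 5147896 to 5148829 (fold 8.69), chromosome 1, 28696186 to 28696690 (8.24), and chromosome 5, 34185044 to 34185426 (7.53). They formed 299 runs of at least 5 peaks, the one with most peaks holding 31 over 515 kb of chromosome 9 (139840337 to 140355208).

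Overlap with the HEK293 library without antibody was 2.68% (2.38 to 3.02) for FLAG-MCM8, against 0.984% under shifts, and 2.89% (2.65 to 3.15) for S9.6, against 1.07%. Places with a peak in all 3 HEK293 lists included chromosome 20, 26189867 to 26190469 in the FLAG-MCM8 list, with a pileup of 301 fragments, and chromosome 21, 9825552 to 9827506, with 326. The library without antibody was so shallow that most sites of background were not detectable at its depth.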

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

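Settings with q of at most 0.05, scaled summit heights, shifts of 10 to 200 kb or a minimum of 2 fragments were chosen after seeing the data. Shares are given in the order KO peaks without WT, WT peaks without KO, KO and WT peaks at no-antibody peaks, FLAG-MCM8 at S9.6, FLAG-MCM8 and S9.6 at no-antibody peaks, and FLAG-MCM8 at S9.6 outside no-antibody peaks. With at least 50% of the query covered they were 87.3, 80.1, 0.760, 0.849, 13.7, 1.39, 1.66 and 13.4%. With the summit inside they were 86.8, 79.9, 0.781, 0.988, 13.5, 1.60, 1.75 and 13.0%. At a −log10 q of at least 5 they were 68.7, 41.3, 1.91, 3.57, 62.5, 2.78, 0.580 and 61.4%. At a fold of at least 5 they were 75.4, 57.3, 2.05, 3.24, 30.5, 1.69, 0.694 and 29.3%. At equal list sizes they were 73.2, 73.2, 1.88, 1.62, 14.3, 0.928, 1.45 and 14.0%. At a q of at most 0.05 in both lists they were 74.7, 58.5, 0.691, 1.18, 36.9, 0.222, 0.0698 and 36.7%. With the query alone at that q they were 65.2, 50.7, 2.22, 2.69, 39.7, 4.72, 3.41 and 38.8%. All contigs changed nothing, since none held a peak. At a −log10 q of at least 5, 72 FLAG-MCM8 and 517 HEK293 S9.6 peaks were left. The numbers were 177 and 576 at a fold of at least 5, and 1800 and 10027 at a q of at most 0.05. The KO and WT peak numbers fell to 367 and 196 at a −log10 q of at least 5, 537 and 309 at a fold of at least 5, and 3472 and 2118 at a q of at most 0.05. The KO to WT ratio outside no-antibody peaks was 1.90, 1.76 and 1.65 there, and 0.997 at equal list sizes, which fix the ratio near 1 by construction. At 4 minima from 1 to 2 fragments at the summit per 1000000 of the library it was 2.24, 2.37, 2.33 and 2.67, at 0.8 it was 1.48, at 3 it was 1 and at 5 it was 0.846; the cause was not tested. Drawing chance positions among the peaks of all lists put the chance level of each overlap above the observed one, at 34.8% for KO in WT, 51.6% for WT in KO, 22.8 and 22.7% for KO and WT in no-antibody peaks, 29.3% for FLAG-MCM8 in S9.6, 58.0 and 57.2% for FLAG-MCM8 and S9.6 in no-antibody peaks and 28.4% for FLAG-MCM8 in S9.6 outside them, where unshared peaks count as possible positions by construction. Removing only no-antibody peaks of at least 2 fragments left the ratio at 1.48 and gave 16.8% for FLAG-MCM8 at S9.6 outside them. Shifts of 10 to 200 kb kept all 8 overlaps above chance. Summits at gene ends at a q of at most 0.05 made up 36.0% of KO-only, 29.9% of WT-only and 64.7% of shared KO peaks. The depth of both no-antibody libraries limits what their lists can show. No paired analysis was possible because each group has 1 library.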

Other observations

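Peaks on the X chromosome made up 0.494% (95% Wilson interval 0.350 to 0.696) of the WT and 0.541% (0.413 to 0.709) of the KO MEF S9.6 list, against 2.57% (2.14 to 3.09) of the MEF list without antibody. In HEK293 the X share was 5.72% for FLAG-MCM8, 3.64% for S9.6 and 5.27% without antibody. Of the 12 gene lists, that of replication-dependent histone genes alone had more members with a peak without antibody than with a KO or a WT peak: 7 of 67 had one, at percentile 100 of random lists matched on gene length, among them H4c14, H4c11, H2ac6 and H2bc4, where H2ac6 and H2bc4 share 1 peak, as do H2ac15 and H2bc15. These peaks without antibody held 4 to 6 fragments, and only the one at H4c14 reached a q of at most 0.05. The random lists do not match how closely the histone genes lie together. The lists were fixed beforehand, and this one was singled out after its values were seen.

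Of the tests in the next 3 paragraphs, that of variation between libraries was written down before its value was looked at, and the others were chosen after the results were seen.

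The KO MEF list held more S9.6 peaks than the WT list. Greater depth of the KO library is argued against, since it held 88.3% of the fragments of the WT library. Lower depth need not give fewer peaks, since the KO list took in peaks of 6 fragments and all WT peaks held at least 7. At 7 or more fragments, the lowest pileup of the WT list, the KO list held 8822 peaks, against 6481 in WT. The numbers were 6990 and 6017 at 8 or more, 3835 and 3531 at 10 or more and 929 and 689 at 15 or more. The size of the KO excess at equal fragment numbers thus depended on the minimum. Gain of single chromosomes or the sex of the embryos is argued against as the source of the whole excess by 19 of 19 autosomes with more KO peaks. The KO to WT ratio was 1.15 on chromosome 15 and 1.32 to 1.68 on the other autosomes. Chromosome 15 held 6.31% (5.74 to 6.93) of the WT and 4.91% (4.50 to 5.36) of the KO list. A difference between the libraries on that chromosome is thus not excluded. Variation between libraries unrelated to genotype, such as a better ratio of signal to background in 1 tube, cannot be told apart from an effect of Mcm8 loss with 1 library per genotype. The loss of Mcm8 stays open as an untested explanation, and outside no-antibody peaks the ratio was 2.24 to 2.67 at minima from 1 to 2 fragments at the summit per 1000000 but 1 at 3 (19 and 19 peaks) and 0.846 at 5 (11 and 13 peaks). The few peaks at 3 and 5 included places with a peak in both lists, such as Kctd16, and say little about weaker peaks.

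The tallest peaks of the HEK293 lists lay on chromosome 17, 3 in the FLAG-MCM8 list near 62496041 and 1 in the S9.6 list at 61994049 to 61994652, where the pileup was 3829 fragments with S9.6 and 932 in the far shallower library without antibody. A repeat or high-signal region of the genome is argued against, since 0 of these 4 peaks had a peak at the same place in the other antibody list. Extra copies of this DNA in some cultures, for example from transfected or integrated constructs, may account for them: the local background reached 599 times the genome-wide one in the antibody lists. That value cannot decide, because the own fragments of the FLAG-MCM8 peaks could fill their local window (up to 128% of it). The 128% is itself uncertain. It counts 6077 fragments at 62496041 to 62496934, the peak whose pileup was not recovered within the tolerance. The share without that peak was not computed. At the S9.6 peak the local background was 131 times the lowest of its list, and 1555 times in the list without antibody. The part made up by the peak's own fragments was not computed there, and no biological explanation was tested. Copies of the MCM8 coding sequence on the transfected plasmid were looked for on chromosome 20, which carries MCM8. The tallest FLAG-MCM8 peak there absent from the other 2 lists held 52 fragments. This value cannot decide the source of the chromosome 17 peaks, since MCM8 sequence maps to chromosome 20. It also leaves out chromosome 20 peaks present in the other lists, and whether those cultures were transfected is not given. The pileup at MCM8 itself was not examined, so the FLAG-MCM8 identity rests on the labels.

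FLAG-MCM8 peaks lay at S9.6 peaks far above random shifts. Regional copy number or regional peak density is argued against, since the highest of 1000 shifts of 10 to 200 kb gave 1.11% against the observed 16.97%. Places that the transposase cuts without an antibody are a candidate explanation for part of the overlap: no-antibody peaks of 1 fragment lay in S9.6 peaks 2.34 times as often as under such shifts. They touched 4.69% (3.78 to 5.82) of S9.6 peaks with FLAG-MCM8 and 2.32% (2.098 to 2.57) of those without, which were narrower (median 381 against 526 bp). How much of the overlap this makes up was not measurable at the depth of that library. Binding of MCM8 at RNA-DNA hybrids stays open, also because the S9.6 peaks were not checked to be hybrids.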
